A study of Mus musculus with 2 samples.

How the data were processed

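RNA was measured in 2 libraries of mouse mammary gland, which the labels call biological replicates of separate samples from C57BL/6J mice aged 8 weeks. Per the labels, the libraries were stranded and paired-end with reads of 76 nt on an Illumina Genome Analyzer IIx, and were made from poly(A)-selected, rRNA-depleted RNA longer than 200 nt with spike-in RNAs. The labels place both libraries in 1 group and state no contrast. Nothing could therefore be tested between groups, and no p-value is given.

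Gene and transcript tables were used as the authors deposited them, with mm10 and GENCODE M4 as assembly and annotation per the text notes beside the tables. Per the file headers, the tables hold expected counts, TPM and FPKM for each gene and transcript, with posterior mean TPM and, for transcripts, the percent of the gene's expression taken by each isoform. The aligner and the quantifier are not given in the sources used here. The expected counts deposited by the authors are fractional. The summed expected counts over genes were 56323489 in replicate 1 and 42400470 in replicate 2. A gene with 3 fragments or fewer in a library was treated as at the floor of detection there. The tables held 43346 genes and 129984 transcripts. A further 26248 entries with a number for a name, all at 0 counts, were left out, and 97 spike-in entries, phiX174 among them, were kept out of gene totals. Gene names, biotypes, coordinates and GC content came from GENCODE M21 on the same build, a later release, which named 42462 of the gene identifiers.

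Contigs and splice junctions were deposited once for the series, on mm9 and without a header. In the contig table, the column read here as signal was deposited by the authors without a unit, and the score column of both tables has no stated meaning in the sources used here. For junctions the count deposited by the authors equalled the sum of the numbers coded R1 and R2 in the junction's name, whose meaning is not stated, in all 465423 entries. Coordinates are given 1-based on mm9 and were not moved to another build. Junctions with a score under 0.1 were the main set, and contigs were used in full.

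Agreement was the Pearson r and Spearman rho across genes of log2(TPM + 1), for genes with a mean TPM of at least 1. A gene lay beyond 2-fold where the 95% Clopper-Pearson interval of its count ratio, from expected counts rounded to whole numbers and scaled by total counts, was wholly beyond 2-fold. For each gene list, the median log2 difference of its members with a mean TPM of at least 1 was placed among 10000 random lists of the same size matched on expression in 20 bins, and lists with fewer than 3 such members were not tested. Percentiles describe these 2 libraries, and the lists overlap. A total of 34 lists of cell types and programmes were fixed before the files were opened, by gene name or by name pattern. Lists of liver transcripts, X homologues of the Y-linked genes and small non-coding RNAs were chosen after the values were seen. Dominant transcripts were compared in genes with more than 1 transcript and at least 5 TPM in both replicates.

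Genes were named by a rule written beforehand. It took up to 5 members of each list with the highest mean TPM, any milk, hormone receptor, Y-linked or X inactivation gene, marker genes at 0, the 20 highest genes apart from mitochondrial ones, the 10 largest differences in each direction among genes beyond 2-fold with a mean of at least 5 TPM, the 5 most abundant genes whose dominant transcript differed, and the 5 highest contigs or junctions. The comparison of TPM with counts and its limits were chosen after the values were seen.

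Alternatives fixed beforehand were other pseudocounts, filters, units, thresholds and scalings, and each replicate left out in turn. Scaling factors came from edgeR (TMM, 1.03 and 0.975), DESeq2 (size factors 1.21 and 0.829) and spike-in totals. For gene lists, the TMM alternative changed the unit from TPM to scaled counts as well as the scaling. The removal of the median difference at each GC content, in 20 bins, and the removal of mitochondrial and muscle genes were added after the data were seen. Beyond the medians of the outermost bins, the GC correction was held at its end value. Tools were R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The replicate comparison was tested on simulated counts for 14510 genes with 200 changed 8-fold, of which 99% were called beyond 2-fold, with 0 unchanged genes called. Of 50 simulated lists of unchanged genes, 1 lay outside the central 95%. The simulated libraries differed only by counting error and the planted changes, with no GC trend in these calls. The simulated lists came from the same genes as the random lists, so that few lay outside was set by design. These checks do not give the error rate of the calls in the 2 real libraries.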

Results

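Poly(A) RNA from mouse mammary gland was sequenced in 2 libraries, labelled as biological replicates 1 and 2 of 1 group. The tissue came from C57BL/6J mice, an inbred laboratory strain, aged 8 weeks, and each library is labelled as RNA pooled from animals of both sexes. Reproductive state was not given in the sources used here. The gene tables held 43346 genes, and the summed expected counts over these genes were 56323489 fragments in replicate 1 and 42400470 in replicate 2. The labels give no contrast, so the data answer which genes the tissue expressed and how far its 2 replicates differed. Paired values below are given for replicate 1 and then replicate 2. Levels are in TPM as deposited by the authors, and coordinates of genes are on mm10.

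By mean TPM, the adipocyte genes Cfd, Fasn and Car3 were the highest nuclear protein-coding genes. Cfd, the adipose serine protease adipsin (chromosome 10, 79890853 to 79892655), stood at 13596 and 29051 TPM, a mean of 21324 ± 10928 (SD, n = 2). Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), stood at 10582 and 16923 TPM, and the stearoyl-CoA desaturase gene Scd1 (chromosome 19, 44394455 to 44407879) at 6466 and 6347 TPM. The carbonic anhydrase gene Car3 reached 7635 and 8896 TPM, but its expected counts were 452272 and 246397. Scaled by total counts, its log2 count ratio of replicate 2 over replicate 1 was -0.4665 (interval -0.4736 to -0.4595). For Car3, TPM and counts therefore gave opposite directions. All 17 white adipocyte markers passed 1 TPM in both replicates and summed to 30984 and 48002 TPM, among them the lipase gene Pnpla2 at 1755 and 2495 TPM, Cidec at 1121 and 1480.4 TPM and the adiponectin gene Adipoq at 1462 and 891 TPM. The 15 lipogenesis genes were likewise all above 1 TPM in both replicates and summed to 23526 and 31073 TPM, with Dgat2 at 1306 and 1921 TPM, Thrsp at 1481 and 1320.0 TPM and Agpat2 at 866 and 1164 TPM. None of the lipogenesis genes lay wholly beyond 2-fold between the replicates, and the percentile of the list's median among matched random lists was 22.5.

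The glandular epithelium was present at lower levels. All 16 luminal epithelial markers passed 1 TPM in both replicates and summed to 1123 and 2069 TPM, led by the keratin genes Krt19 at 385 and 660.3 TPM, Krt8 at 154 and 282 TPM and Krt18 at 153 and 247 TPM, followed by the claudin gene Cldn3 at 83.3 and 251 TPM and Spint2 at 84.9 and 204 TPM. Of these markers 14 were higher in replicate 2, 2 of them by an interval wholly beyond 2-fold, but the list's median log2 difference of 0.59 (replicate 2 minus replicate 1) lay inside the central 95% of random lists. With the GC trend removed, 10 of 16 were higher in replicate 2, at a median of 0.19. The 14 basal myoepithelial markers, the contractile cells around the ducts, were also all above 1 TPM in both and summed to 899.8 and 839 TPM. The smooth muscle actin gene Acta2, at 476 and 353 TPM, and Tagln, at 144 and 175 TPM, took most of that sum. Both are also expressed outside the epithelium, so the sum does not measure myoepithelium alone. Krt14 stood at 58.5 and 47.7 TPM, the oxytocin receptor gene Oxtr at 40.7 and 60.2 TPM and Krt5 at 57.3 and 35.8 TPM. Krt14 and Krt5 are also expressed in skin. All 10 luminal progenitor markers were above 1 TPM in both, with a median log2 difference of -0.02. The transferrin gene Trf, also expressed outside the epithelium, took most of that list's TPM at 1178 and 2223 TPM, and Lcn2 stood at 148 and 189 TPM, Gata3 at 48.0 and 128 TPM, Lbp at 88.3 and 57.4 TPM and Wfdc18 at 78.3 and 47.5 TPM.

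Hormone-sensing luminal genes differed between the replicates in both directions. Of the 10 members with a mean TPM of at least 1, 4 were wholly beyond 2-fold higher in replicate 2 and 2 in replicate 1, and the list's median log2 difference was 0.29. The growth factor gene Areg, induced by oestrogen in this tissue, stood at 58.1 and 201 TPM, the transcription factor gene Foxa1 at 25.7 and 81.9 TPM and Cited1 at 116 and 130.1 TPM. The progesterone receptor gene Pgr stood at 11.3 and 44.2 TPM, with a log2 count ratio of 1.38 (95% interval 1.31 to 1.46), whereas the prolactin receptor gene Prlr was lower in replicate 2 at 58.0 and 26.9 TPM, with a log2 count ratio of -1.15 (-1.20 to -1.11). With the GC trend removed, 5 of 10 members were higher in replicate 2, at a median of 0.12. The log2 TPM difference then went from -1.08 to -0.42 for Prlr, and from 1.87 to 1.69 for Pgr.

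Of 16 hormone and growth factor receptor genes, 15 passed 1 TPM in both replicates. The oestrogen receptor gene Esr1 stood at 22.9 and 29.6 TPM, while Esr2 was covered by 2 fragments in replicate 1 and 0 in replicate 2. The growth hormone receptor gene Ghr stood at 134 and 81.5 TPM, Thra at 65.8 and 123 TPM, Erbb2 at 16.7 and 27.1 TPM, Insr at 19.1 and 22.1 TPM, Nr3c1 at 19.8 and 18.8 TPM and Erbb3 at 17.2 and 16.9 TPM. Lower in the list were Vdr at 6.01 and 6.82 TPM, Nr3c2 at 5.54 and 4.85 TPM and Igf1r at 3.27 and 4.89 TPM. Egfr stood at 49.1 and 156 TPM, but its expected counts were 6502 and 3640, a log2 count ratio of -0.43 (-0.49 to -0.37), so TPM and counts gave opposite directions. Such opposite directions, by over 0.5 in log2 TPM and over 0.25 in log2 counts, were found in 78 of 13778 genes with over 100 fragments.

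Most casein genes and Wap were near 0, whereas Csn3 and Lalba were measurable. The whey acidic protein gene Wap and the casein gene Csn1s2a had no fragment in either replicate, which at a floor of 3 fragments per library leaves their levels below the depth of these data. The casein genes Csn2 (5 and 3 fragments), Csn1s1 (5 and 1) and Csn1s2b (1 and 0) were close to that floor. Csn3 stood at 78.6 and 40.01 TPM and the alpha-lactalbumin gene Lalba at 10.4 and 2.26 TPM. Among the expressed members, Lalba alone had an interval wholly beyond 2-fold, at a log2 count ratio of -2.29 (-2.84 to -1.78). Among genes of milk fat secretion with roles outside lactation, Mfge8 at 488 and 854 TPM and Plin2 at 349.7 and 349 TPM were above Csn3. Xdh, at 38.3 and 33.9 TPM, was below Csn3. Btn1a1 stood at 10.7 and 6.75 TPM, Spp1 at 7.95 and 3.69 TPM and Cel at 0.41 and 0.11 TPM. Glycam1, expressed both in mammary epithelium and in lymph node vessels, stood at 683 and 559.5 TPM. The list's median log2 difference of -0.44 lay at percentile 5.04, and on TMM-scaled counts in place of TPM it was -0.58 at percentile 2.34, outside the central 95%. It lay inside with no filter, at -0.13, and with the GC trend removed, at -0.29 and percentile 11.4.

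Connective tissue, vessels and nerve were represented by complete marker lists. All 16 fibroblast and matrix genes passed 1 TPM in both replicates and summed to 7098 ± 246 TPM (SD, n = 2), with Sparc at 2934 and 3223 TPM, Dcn at 951 and 485 TPM, Fn1 at 386 and 693 TPM, Mmp2 at 374 and 440.5 TPM and Col1a2 at 357 and 383 TPM. All 13 blood endothelial markers were present, summing to 1065 ± 103 TPM, led by Egfl7 at 370.3 and 350.1 TPM and Eng at 153 and 227 TPM. The 7 lymphatic endothelial markers summed to 302 ± 51.9 TPM, of which Ccl21a gave 228 and 308 TPM and Lyve1 17.8 and 10.7 TPM. The 6 pericyte markers summed to 194 ± 12.2 TPM, with Notch3 at 40.4 and 80.4 TPM and Pdgfrb at 58.5 and 56.0 TPM. All 9 Schwann cell genes passed 1 TPM in both, at a median of 12.95 and 6.48 TPM. The myelin gene Pmp22, also expressed outside Schwann cells, stood at 172 and 194 TPM. None of these 5 lists left the central 95% of random lists, except that the Schwann cell list reached percentile 0.60 once the GC trend was removed, at a median of -0.57.

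Lymphocyte and macrophage markers were present in full. All 13 B cell markers and all 15 T cell markers passed 1 TPM in both replicates, summing to 1131 and 1594 TPM and 359 and 702 TPM. The immunoglobulin gene Ighm stood at 491 and 632 TPM, Cd79a at 169 and 379.5 TPM, Tcf7 at 62.3 and 176 TPM and the lymphocyte homing receptor gene Ccr7 at 69.1 and 160.4 TPM. The lymph node stroma genes measured, 7 in number, summed to 1184 and 1694 TPM. Besides Glycam1 and Ccl21a they were led by the chemokine gene Ccl19 at 163 and 424 TPM, Ltb at 88.2 and 367 TPM and the B cell attractant Cxcl13 at 16.8 and 22.04 TPM. Ltb is expressed by lymphocytes, so the list does not measure stroma alone. 6 of the 7 were higher in replicate 2, and the median log2 difference of 0.91 lay at percentile 98.0 of random lists, and 99.5 with the GC trend removed. Without an expression filter the percentile was 97.2, inside the central 95%. The T cell list lay at percentile 90.0 with a median of 0.49, and at 99.9 with the GC trend removed, outside the central 95%. The 12 macrophage markers, all above 1 TPM in both, summed to 1671 ± 12.2 TPM (SD, n = 2), with Lyz2 at 749.8 and 496 TPM and the complement gene C1qc at 259 and 423 TPM. Of these markers 8 were higher in replicate 1, 3 wholly beyond 2-fold, with a median of -0.44 at percentile 3.13, inside the central 95%. Mast cell genes, 5 of 7 above 1 TPM in both, summed to 209.5 and 169.7 TPM, with Tpsb2 at 107 and 118 TPM and Mcpt4 at 49.1 and 26.9 TPM, and their median of -0.84 lay at percentile 1.03, against 9.70 without the filter. The 8 neutrophil genes, 6 of them above 1 TPM in both, summed to 27.4 and 19.3 TPM. Red cell genes summed to 1709 and 4424 TPM, with Hbb-bs at 476 and 933 TPM. The near-identical Hba-a1 (437 and 1667 TPM) and Hba-a2 (722 and 1736 TPM) are uncertain because they share reads. All 5 expressed red cell members were higher in replicate 2, at percentile 95.4, and 98.8 with the GC trend removed.

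**Figure D1:**
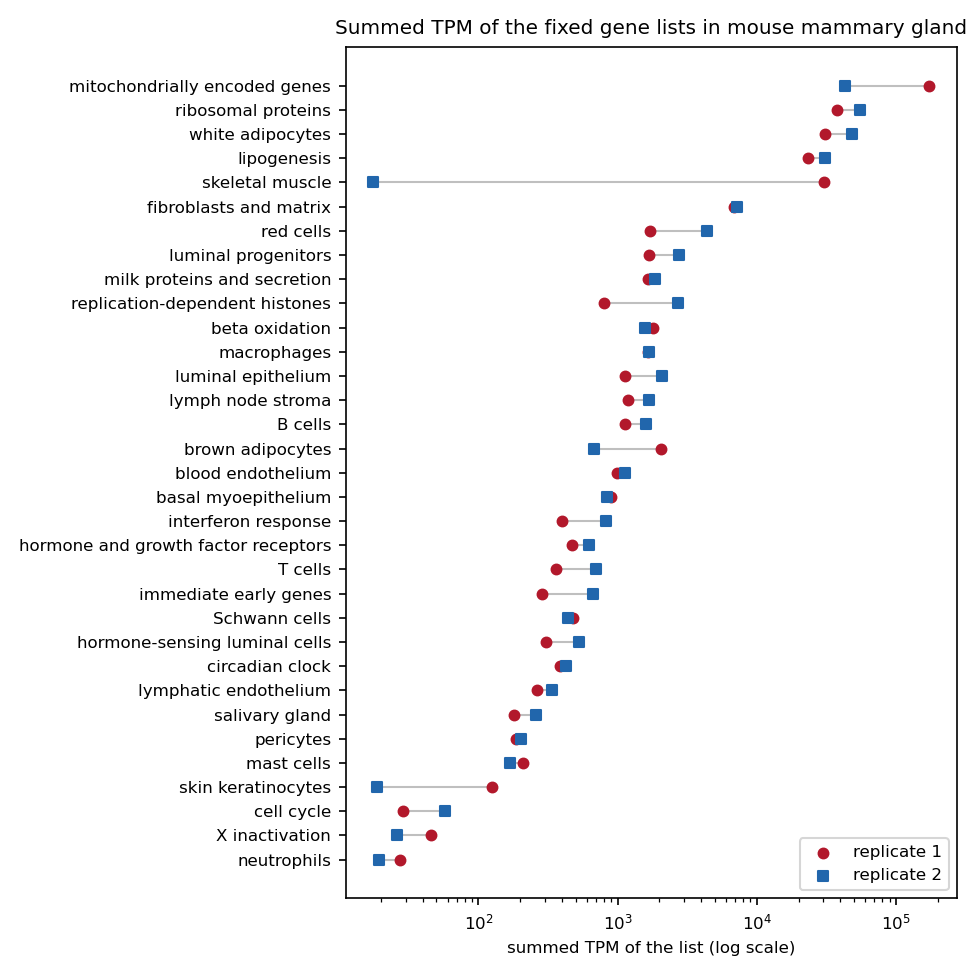
Summed TPM (log scale) of each gene list fixed beforehand that exceeded 1 TPM on average, with 1 point for replicate 1 (red circle) and 1 for replicate 2 (blue square) joined by a grey line. Skeletal muscle genes lay at 30474 and 17.6 TPM in replicates 1 and 2, whereas the fibroblast and matrix genes lay at 6924 and 7272 TPM.

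Skeletal muscle transcripts separated the 2 replicates. All 14 members of the muscle list with a mean TPM of at least 1 were higher in replicate 1 with intervals wholly beyond 2-fold, and the list took 3.05% of TPM there against 0.00176% in replicate 2. The skeletal actin gene Acta1 (chromosome 8, 123891769 to 123894751) stood at 11332 and 5.93 TPM, a log2 count ratio of -10.98 (-11.18 to -10.79). The creatine kinase gene Ckm stood at 6496 and 2.03 TPM, the calcium pump gene Atp2a1 at 6394 and 1.95 TPM, Mylpf at 1260.0 and 0.86 TPM and Tnni2 at 1225 and 1.20 TPM. The list's median log2 difference was -8.65, at percentile 0 of random lists. Skin keratinocyte genes were also higher in replicate 1, at 125 and 18.8 TPM in sum and 6 of 8 members wholly beyond 2-fold, among them Krtdap at 52.8 and 1.13 TPM, Krt77 at 23.1 and 1.15 TPM and Krt10 at 17.8 and 2.15 TPM. Krt2 had no fragment in either replicate.

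The replicate that carried the muscle transcripts also held more mitochondrial RNA and higher levels of most brown adipocyte genes. Mitochondrially encoded genes took 17.4% of TPM in replicate 1 and 4.28% in replicate 2, and all 15 expressed members were wholly beyond 2-fold higher in replicate 1. The list's median log2 difference was -1.99, and -1.24 with the GC trend removed, at percentile 0 either way. The expressed members had a median GC content of 36.0%, below the median of the lowest GC bin. The correction there was held at an end value and may be incomplete. Without an expression filter the list's median was 0.0, since its 22 transfer RNA genes had no fragment. The cytochrome oxidase gene mt-Co1 stood at 57397 and 13167 TPM and mt-Co3 at 37752 and 6201 TPM. The brown adipocyte list summed to 2036 and 676 TPM. Of its 10 expressed members 8 were higher in replicate 1, 6 of them wholly beyond 2-fold. Kcnk3 at 42.9 and 76.9 TPM and Slc27a2 at 4.58 and 5.95 TPM were higher in replicate 2. The uncoupling protein gene Ucp1, the defining gene of brown fat, stood at 709.9 and 100.5 TPM, a log2 count ratio of -2.90 (-2.95 to -2.86), and Cidea at 189 and 59.5 TPM. Cox8b (695 and 361 TPM), Cpt1b (223 and 37.7 TPM) and Cox7a1 (140.1 and 14.7 TPM) are also expressed in muscle. The beta oxidation list had a median of -0.54 at percentile 0.10, with 4 of 12 members wholly beyond 2-fold higher in replicate 1 by counts, among them Hadhb at 252 and 137 TPM and a log2 count ratio of -1.66 (-1.71 to -1.61). White adipocyte genes had a median of -0.26 at percentile 0.725, although their summed TPM was higher in replicate 2, and the percentile was 22.1 with the GC trend removed.

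**Figure D2:**
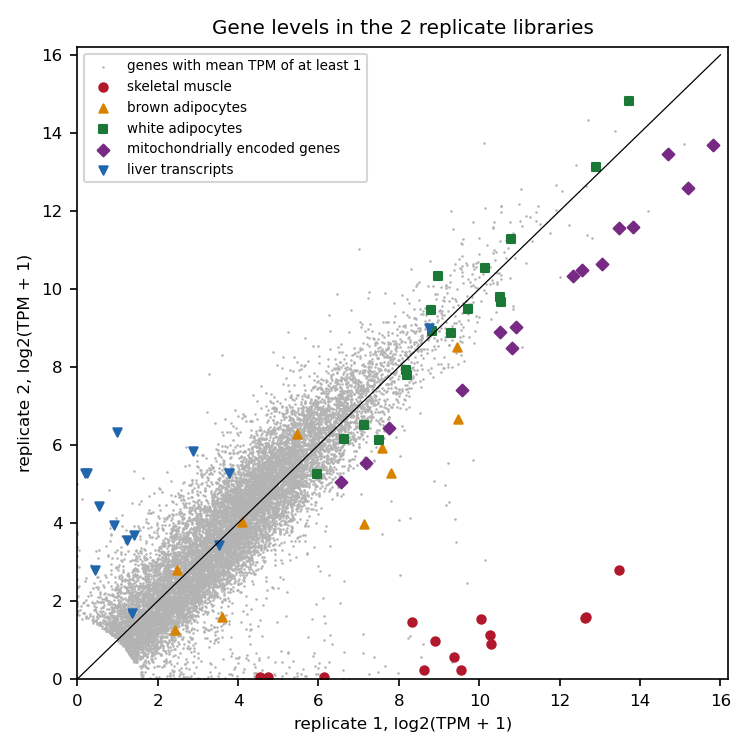
Each grey point is 1 gene with a mean TPM of at least 1, with log2(TPM + 1) in replicate 1 on the x axis and replicate 2 on the y axis, coloured markers for the members of 5 lists and a line of equality. The skeletal muscle genes lie far under the line at a median log2 difference of -8.65, and the liver transcripts, a list chosen after the values were seen, lie above it at 2.36.

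The 2 replicates differed with the GC content of the transcripts. Over 13271 protein-coding genes, GC content and the log2 difference of replicate 2 minus replicate 1 had a Spearman rho of 0.594 across genes, which are not independent replicates. The median difference was -0.68 in the lowest of 10 equal groups by GC content and 1.02 in the highest. Transcript length showed no such relation, with a rho of -0.0103.

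**Figure D3:**
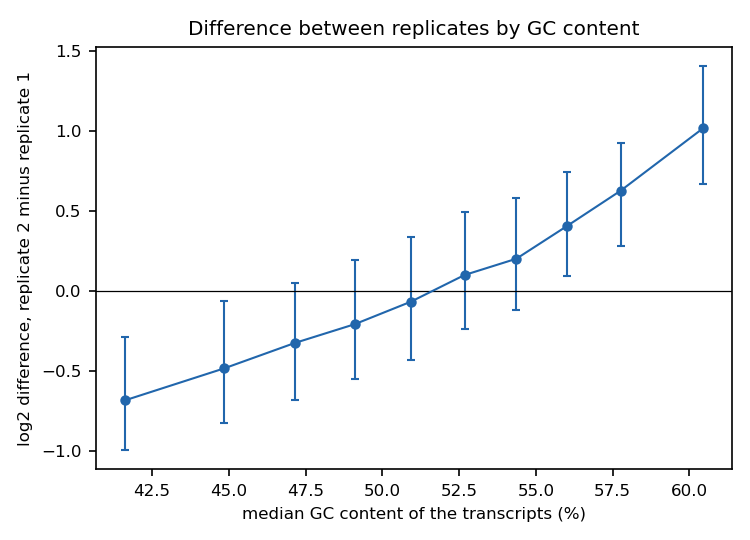
Median log2 difference in TPM + 1 between the replicates (points) and the interquartile range (bars) in 10 equal groups of protein-coding genes ordered by GC content, with the median GC content in percent on the x axis. The median is -0.68 in the group of lowest GC content and 1.02 in the highest.

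Histone genes were higher in replicate 2, and most immediate early and cell cycle genes lay in the same direction. Of 55 expressed members of the replication-dependent histone list, whose mRNAs mostly end without a poly(A) tail, 53 were higher in replicate 2 and 39 wholly beyond 2-fold. Their median log2 difference was 1.84, and 1.21 with the GC trend removed. It was 1.22 on TMM-scaled counts in place of TPM and 1.46 without a filter. Examples were Hist2h2aa1 at 209.9 and 563 TPM, Hist1h2bc at 256 and 383 TPM and Hist1h2ap at 28.4 and 330.5 TPM, with values per gene uncertain because histone paralogs share reads. The name pattern that defined this list also matched H1f0, a polyadenylated linker histone gene, at 36.3 and 89.4 TPM. Immediate early genes, which respond within minutes to stimuli, had a median of 0.81 at percentile 98.4, with 8 of 10 members higher in replicate 2 and 5 wholly beyond 2-fold. Junb stood at 36.9 and 185 TPM, Zfp36 at 74.3 and 185 TPM, Dusp1 at 61.8 and 60.7 TPM and Egr1 at 24.9 and 78.9 TPM. The cell cycle list had a median of 0.55 at percentile 98.0, and inside the central 95% on TMM-scaled counts in place of TPM (94.4) or without a filter (91.3). Of its 8 expressed members 6 were higher in replicate 2 and 2 wholly beyond 2-fold. Its highest members were Aurkb at 4.09 and 16.5 TPM and Ccna2 at 3.49 and 16.6 TPM. The 85 ribosomal protein genes summed to 38035 and 55629 TPM, led by Rps2 at 2703 and 3436 TPM. Their median of 0.12, against 0.33 for matched random lists, lay inside the central 95% at percentile 3.55. It lay outside without a filter, at percentile 1.67. With the GC trend removed it lay inside, near the opposite limit, at percentile 97.2.

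Across all fixed lists, 11 of 32 tested lists lay outside the central 95% of random lists, 4 above and 7 below. Without an expression filter the number was 8 of 34, 2 above and 6 below. With the GC trend removed, an alternative added after the data were seen, the number was 13. The Y-linked and salivary gland lists had fewer than 3 expressed members and were tested only without the filter, where both lay inside the central 95%. Both medians were 0.0 there because most members were at or near 0 TPM, so these calls cannot show a shift. Among the salivary genes, Aqp5 stood at 122 and 238 TPM and Amy1 at 58.9 and 20.97 TPM, and the other members were under 1 TPM in both replicates.

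Between the replicates, 2635 of 14510 genes with a mean TPM of at least 1 had a 95% interval of the count ratio wholly beyond 2-fold, 1266 higher in replicate 2 and 1369 in replicate 1. The 10 with the largest log2 differences in TPM toward replicate 1 were the muscle genes Atp2a1, Ckm, Acta1, Mylpf, Pvalb, Tnni2, Casq1, Actn3, Tnnc2 and Myh4. Toward replicate 2 they were Apoa2 at 0.98 and 80.3 TPM, Ttr at 0.14 and 37.9 TPM, Ahsg at 0.18 and 37.6 TPM, Apoc4 at 0.09 and 23.7 TPM and Apoa1 at 0.45 and 20.6 TPM, which are liver secretory products, besides Hist2h2aa2 at 11.2 and 317 TPM, Usp1 at 8.71 and 225 TPM, Gm20521 at 0.74 and 28.0 TPM, Gm21451 at 1.64 and 39.5 TPM and the lincRNA Gm26917 at 128 and 2075 TPM. The interval covers counting error in these 2 libraries only. With DESeq2 size factors the split was 1626 and 1052, and without mitochondrial and muscle genes it was 888 and 1963. Scaling by spike-in counts gave 4909 genes, 4482 of them higher in replicate 2, and removing the GC trend gave 1545.

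Over the same genes, log2(TPM + 1) of the replicates had a Pearson r of 0.881 and a Spearman rho of 0.878 across genes. Of 21474 protein-coding genes, 12512 had at least 1 TPM in both replicates, from 13214 in replicate 1 and 12917 in replicate 2, and 4088 had no fragment in either. The 10 highest genes took 23.6% of TPM in replicate 1 and 14.3% in replicate 2, a mean of 19.0% ± 6.62 (SD, n = 2). Besides the adipose and muscle genes named above, the highest nuclear genes by mean TPM were the annotated pseudogene Gm29216 at 34767 and 13501 TPM, the 7SK RNA gene Rn7sk at 6686 and 20474 TPM, Gm10222 at 18717 and 4087 TPM, Gm42418 at 1104 and 13706 TPM, Rplp1 at 5411 and 9294 TPM and Actb at 3838 and 6482 TPM. Values of Gm29216 and Gm10222 are uncertain because they resemble mitochondrial genes and can share their reads.

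Genes on the Y chromosome were almost absent from libraries labelled as mixed sex. The 6 Y-linked genes, among them Ddx3y (chromosome Y, 1260771 to 1286629) and Kdm5d, were covered by 2 fragments in replicate 1 and 2 in replicate 2, from Ddx3y with 2 and 1 and Eif2s3y with 0 and 1. Kdm5d, Uty, Usp9y and Zfy1 had none. Xist, the RNA that coats the inactive X chromosome of female cells (chromosome X, 103460366 to 103483254), stood at 40.5 and 21.9 TPM, with 26834 and 10298 fragments. Ftx stood at 3.02 and 1.95 TPM, Jpx at 2.30 and 2.12 TPM and Tsix at 0.04 and 0.06 TPM.

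Of 6906 genes with more than 1 annotated transcript and at least 5 TPM in both replicates, 5246 had the same dominant transcript in both, or 75.96% (95% Wilson interval 74.9% to 77.0%, counting error only). Among genes whose dominant transcript differed, Car3 was the most abundant. Its transcript of 1679 nt made up 70.8% of the gene in replicate 1 and 27.5% in replicate 2, and its transcript of 804 nt made up 2.05% and 60.6%. Car3 was higher in replicate 2 by TPM and lower by counts. Whether the shift in transcripts accounts for this was not tested. For the ATP synthase gene Atp5b the dominant transcript was 1131 nt long in replicate 1, at 49.1%, and 343 nt in replicate 2, at 70.3%, and Sparc, Rack1 and Atp5d followed in abundance. The transcript dominant in replicate 2 had the higher GC content in 1198 of 1611 such genes, or 74.4%. It was the shorter transcript in 947 of 1660 genes, or 57.0%, and for Rack1 it was the longer, at 1447 nt against 766 nt.

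Spike-in RNAs, added at amounts not given in the sources used here, had a Pearson r of 0.990 between the replicates over 96 ERCC controls. They took 1.55% of all counts in replicate 1 and 0.919% in replicate 2.

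The contigs, stretches of the mm9 genome covered by reads, were deposited once for the series with no replicate named. They numbered 700384, with 357339 on the plus strand, a median length of 219 nt and a covered length of 246 Mb. The authors' signal per contig was highest at 14200 on chromosome 16 from 11143991 to 11144421, then 5140 on chromosome 9 from 110183743 to 110183889. The third was 4880 on the mitochondrial chromosome from 1094 to 6943, and the next were on chromosome 10 from 79353524 to 79357565 at 3160 and on chromosome 3 from 5860319 to 5860829 at 2840. The Y chromosome held 29 contigs with a highest signal of 2.18. The 311955 contigs with a score under 0.1 held 98.9% of the summed covered bases.

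Of 465423 splice junctions on mm9, 139927 had a score under 0.1, and these held 96.7% of the 35893643 junction reads. Their median intron length was 1226 nt, against 5984 nt for the rest. The highest counts were on chromosome 10 from 79354358 to 79354447 with 381673 reads, at 2 overlapping introns that start at 79353726 with 352635 and 279540 reads, and on chromosome 19 from 44472609 to 44474631 with 238535 and from 44481251 to 44481875 with 184426. No mm9 gene annotation was used here, so these positions are given without gene names.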

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

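Both signals were looked for only after the tables had been opened. Fragments assigned to the phage genome phiX174, an entry that no comparison reported on and that entered only the spike-in totals, numbered 77 in replicate 1 and 124 in replicate 2, above the 3 fragments that a count of 0 leaves possible. Junction reads on the mitochondrial chromosome, whose genes have no introns, numbered 3100 over 827 junctions, 2689 and 411 under the codes R1 and R2, whose meaning is not stated, and were likewise above that limit. Of these junctions 32 had a score under 0.1. No explanation was tested for either signal.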

How the results depend on the processing

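The removal of the GC trend and of mitochondrial and muscle genes was chosen only after the results were seen. No paired analysis was possible because the labels give 1 group. The Pearson r of 0.881 between replicates was 0.845 with a pseudocount of 0.1, 0.962 with no filter, 0.813 at a mean TPM of at least 5, 0.885 on FPKM, 0.889 without mitochondrial and muscle genes and 0.896 with the GC trend removed. The 2635 genes beyond 2-fold became 4909 with spike-in scaling, which moved the median log2 ratio by 0.76, and 1545 with the GC trend removed. DESeq2 factors moved that median by 0.13 and the removal of mitochondrial and muscle genes by -0.18. Of 128 list medians under alternatives, 110 kept sign and call, 7 changed sign inside the central 95%, 5 lost the call and 5 gained it. The remaining 1, the mitochondrial list, lost sign and call at 0.0 with no filter, because transfer RNA genes at 0 counts then entered. The same dominant transcript was found in 85.0% of genes where it took at least 60% in either replicate. For these shifts the cause was not tested. Contigs numbered 311955 with a score under 0.1 and 366986 at 200 nt or more, and junctions 465423 with no score threshold, since fewer or more entries then pass. Leaving out each replicate gave 12917 to 13214 detected protein-coding genes, 30 to 31 lists with at least 50% of members at 1 TPM or more, and 14.3% to 23.6% of TPM in the 10 highest genes. With 2 libraries, depth limits genes at 3 fragments or fewer, such as Wap and Csn1s2a.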

Other observations

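The tests of muscle tissue, of carry-over, of the Y-linked genes and of GC bias in the small non-coding RNAs were chosen only after the results were seen. Liver transcripts, a list chosen after the values were seen, summed to 469 and 839.8 TPM in replicates 1 and 2, and 10 of 13 expressed members were wholly beyond 2-fold higher in replicate 2. The albumin gene Alb, singled out after its values were seen, stood at 6.38 and 56.3 TPM. Hp took most of the list's summed TPM in both replicates, at 432 and 512 TPM, whereas the list's median TPM was 0.98 and 14.4. The circadian clock list had a median log2 difference of 0.03, with Nr1d1 at 168 and 150.2 TPM and Dbp at 42.9 and 104 TPM. The interferon response list had a median of -0.15, and 8 of 12 members were higher in replicate 1, 4 wholly beyond 2-fold, against 1 wholly beyond 2-fold in replicate 2. Its highest members went the other way, with Bst2 at 182 and 468 TPM and Irf7 at 75.3 and 181 TPM. The X inactivation list lay at percentile 22.4. Junction reads on the Y chromosome numbered 47.

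The skeletal muscle transcripts of replicate 1 were weighed against 3 sources. Removing the GC trend left the list's median log2 difference at -8.92, so a GC bias does not account for it. Muscle tissue in the RNA would raise all abundant muscle genes, but that 14 expressed members were at least 8-fold higher in replicate 1 restates the pattern and adds no support. Reads carried over from a muscle library could give the same 3.05% of TPM, and both sources stay open and cannot be told apart here. No biological explanation was tested, since the labels give 1 group.

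The near absence of Y-linked transcripts was set against the label of pooled sexes. With 4 fragments on the Y-linked genes over both libraries, the chromosome was not missing from the reference, and depth does not account for the result, since the lowest count of an X homologue was 323 fragments. The X homologues, chosen after the values were seen, summed to 140.2 and 126 TPM. Y-linked fragments were 0.0101% of those on the X homologues, a share that RNA almost wholly from females could give. Over all 1569 genes listed on the Y chromosome, fragments numbered 9.77 in replicate 1 and 2 in replicate 2. These low counts argue against a sizeable share of male RNA in either library. Whether the pools held only females stays open, since this source was drawn from these same values. How the tissue was pooled is not given in the sources used here.

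Histone genes and small non-coding RNAs were both higher in replicate 2. The small non-coding RNAs, a list chosen after the values were seen, summed to 10630.2 and 33756 TPM, with the RNase subunit gene Rmrp at 650.2 and 2948 TPM and Rn7s1 and Rn7s2, which share reads and are uncertain, at 1490.5 and 4442 TPM each. Removing the GC trend left the histone median at 1.21, so the trend alone does not account for it, but took the small non-coding RNA median from 1.59 to 0.65, where GC bias stays open. With the trend removed, 96.7% of expressed members of both lists, 59 of 61, were higher in replicate 2. More RNA without a poly(A) tail could give this, but stays open because the small RNAs were chosen for the pattern, and no biological explanation was tested.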
